A study of Drosophila melanogaster with 2 samples.

How the data were processed

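Chromatin immunoprecipitation and sequencing had been done on 2 biological replicates of whole embryos, aged 0 to 24 h, of a Drosophila melanogaster strain with a Ptx1-eGFP insertion. The labels' protocols name an antibody against GFP, while the antibody field names Ptx1. The replicate numbers were taken from the labels, and both samples form 1 group.

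The authors deposited peak lists on dm6 after irreproducible discovery rate (IDR) analysis, as ranked and thresholded lists, for each replicate and for the series. The aligner, the peak caller and their versions are not given in the sources used here. Each deposited peak has a strength score with no stated unit and a second score, the IDR on a scale capped at 1000. The scaled score equalled -125 times log2 of the IDR recorded beside it, within 1 in all 91374 ranked peaks of the replicate pair. The deposited lists also hold a −log10 q value per peak, which broke ties and served as an alternative ranking. Every thresholded peak had a scaled score of at least 830. Of 6994 replicate-pair peaks at or above 830 the conservative list kept 6840, and the further filter is not given in the sources used here. Each replicate had its own list, and the series lists combine both. Read depth is unknown, so intervals cover counting of peaks or genes alone.

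Peaks were compared with the genome sequence of the same assembly and with Ensembl 115 genes on the arms 2L, 2R, 3L, 3R, 4, X and Y. Peaks on other scaffolds were left out of these steps. Overlap and position were tested against 1000 seeded placements on the same arm with one-sided permutation tests, and annotation classes with two-sided ones. Arms were tested with exact binomial tests. For 17 motifs, windows reaching 50 bp either side of the summit were set against equal windows 500 bp to a randomly drawn side with the exact McNemar test. Gene lists, RNA classes and passing against failing peaks were tested with Fisher's exact test, two-sided. Adjusted p-values are Benjamini-Hochberg over the arms, motifs, lists or classes. A gene was called bound when a summit lay within 1000 bp of a TSS (500 bp for RNA genes), which 3729 of 13968 coding genes (26.7%) met. Intervals of shares are exact Clopper-Pearson at 95%. Failing peaks were those of the replicate pair with a scaled score below 830.

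The 20 gene lists, the rule for named genes and the tests were fixed before the data were examined, except for the tests and alternatives said to be chosen after. The rule takes Ptx1, the coding gene with the nearest TSS for each of the 25 highest-score conservative peaks, and up to 4 bound members per list by score. Genes named outside it, near peaks absent from the conservative list or caught by a list through their symbol alone, were chosen after their values were seen. Alternatives covered the peak list, overlap criteria, windows, backgrounds and each replicate alone. The functions were tested on simulated data with 6000 peaks. TAATCC planted in 10% of windows was recovered as a rise of 9.68%, and 0 motifs, 0 lists and 0 arms passed with random peaks. Random peaks were drawn without regard to GC content, while real summits had lower GC content than their flanks. The random run therefore cannot show how often the flank comparison calls motifs under such a difference. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.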

Results

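Sites bound by a Ptx1 fusion protein were mapped in whole Drosophila melanogaster embryos. Ptx1 is a paired-like homeodomain protein, and the transgenic flies expressed it fused to enhanced green fluorescent protein (eGFP). Chromatin from embryos aged 0 to 24 h was sheared to fragments of 200 to 800 bp. By the labels' protocols it was precipitated with an antibody against the tag, while the antibody field names Ptx1. The 2 samples formed 1 group of biological replicates, so the design holds no contrast between conditions. The comparisons it allows are the agreement of the replicates, the position of the bound sites relative to genes, their sequence, and binding across groups of genes. No control sample was analysed here, and read totals are unknown because peak lists carry none. Coordinates are 1-based on dm6.

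The conservative list of peaks that passed the irreproducible discovery rate (IDR) threshold held 6840 peaks, and 6824 of them lay on chromosome arms 2L, 2R, 3L, 3R, 4, X and Y. The other thresholded list of the series held 7439, a ratio of 1.09 (95% interval 1.052 to 1.124 from counts). These lists share 6185 identical peaks, so the interval treats overlapping lists as independent counts. Replicate 1 had 5480 peaks in its own thresholded list and replicate 2 had 4825, a ratio of 1.14 (95% interval 1.09 to 1.18). The conservative peaks had a median width of 370 bp and covered 2.15 Mb.

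The strongest sites were shared by both replicates. When replicate 1 peaks were divided by score into 4 equal groups, 99.6% of the strongest group overlapped a thresholded replicate 2 peak, and 37.4% of the weakest group did. Over the full lists, 75.1% of replicate 1 peaks (4104 of 5463, exact Clopper-Pearson 95% interval 74.0 to 76.3) overlapped a replicate 2 peak by at least 1 bp, against 2.16% ± 0.187 (SD over 1000 random placements). The reverse share was 83.5% (4024 of 4822, interval 82.4 to 84.5). Both had a one-sided permutation p of 0.001, the smallest that 1000 placements can give. Peaks of replicate 1 with a replicate 2 summit within 370 bp lay a median of 18 bp from it. In the longer ranked list of replicate 2, 95.4% of the weakest replicate 1 group had an overlapping peak, against 21.0% at random. Across the 91374 peaks ranked from the replicate pair, the replicates' scores correlated with Pearson's r = 0.61 on the log10 scale and Spearman's rho = 0.36. Across the 6840 conservative peaks r was 0.92 and rho 0.87, but IDR selects peaks by agreement of the replicates' scores, so these values are built in. Across the peaks below the IDR minimum r was 0.18 and rho 0.19. These correlations are across peaks, which are not independent replicates.

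**Figure D1:**
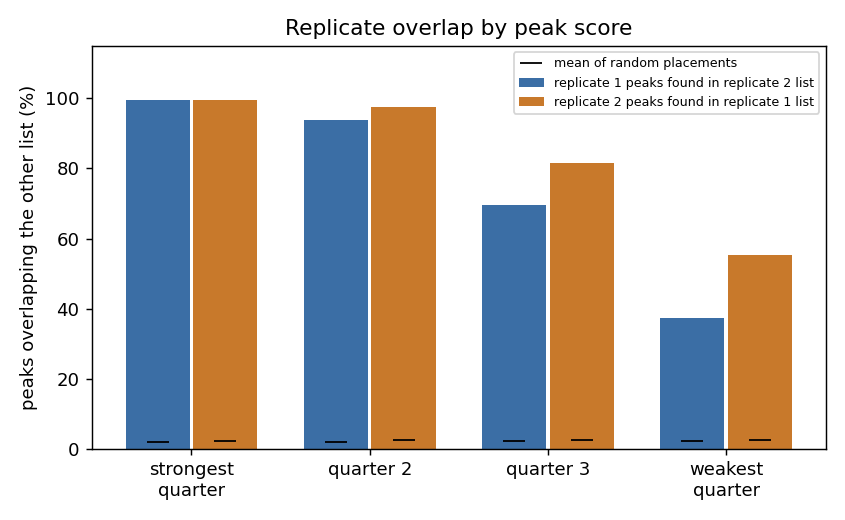
Percent of each replicate's thresholded peaks (y axis) that overlapped a thresholded peak of the other replicate, for 4 equal groups of peaks ranked by score (x axis), with replicate 1 in blue, replicate 2 in orange and the mean of random placements as black dashes. The share fell from 99.6% to 37.4% for replicate 1 and from 99.4% to 55.3% for replicate 2.

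Most of the highest peaks lay near promoters. The top site was 39 bp upstream of the start of Ugalt, a UDP-galactose transporter gene (X, 2703686 to 2704076, intergenic), with a score of 3662. CG14100 followed on 3L (19590433 to 19590814, score 3315, 95 bp upstream), then mRpL41, which encodes a mitochondrial ribosomal protein, on 2R (15217544 to 15217934, score 3203, 131 bp upstream). Other nearest genes were Adf1 (score 2546, in an intron 783 bp downstream of a start), the Polycomb group gene ph-p (2473, intronic), the chromodomain gene Chro (2338, in the 5' UTR), the HMG-box gene HmgZ (2160, intronic) and tara (2103, 3168 bp upstream). The rest were eIF6 (2273), PNPase (2213), mRpL23 (2063), CG7601, CG11050, Tcs5, Art3, CenG1A, CG5611, CG13323, GstE13, Shc, CG8320, CG18549, CG32772, CG4004 and CG9147. Of these 25 peaks, 20 had their summit within 1000 bp of a coding transcription start site (TSS) and 17 within 250 bp. The farthest, 11912 bp from a start, was assigned to CG13323. All 25 had a thresholded peak with a summit within 100 bp in both replicates. The scores are the authors' own value per peak and serve here only to rank peaks within a list.

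Ptx1 itself (FBgn0020912, 3R, 30912754 to 30930682) was bound at its own promoter. A conservative peak at 30912398 to 30912767 had its summit 171 bp upstream of the Ptx1 start, with a score of 123 and rank 3597 in the list. Each replicate's own thresholded list also had a summit within 1000 bp of the Ptx1 start, with highest scores of 53.5 in replicate 1 and 66.4 in replicate 2. These replicate peaks were not matched by position to the conservative peak. Within the gene and 5000 bp on either side there were 6 conservative peaks, 3 of them upstream of the start and 3 in introns. Whether the inserted construct carries sequence of this locus is not given in the sources used here.

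Bound sites concentrated near gene starts and avoided coding sequence. Summits within 1000 bp of a TSS made up 51.3% of the conservative peaks (3498 of 6824, exact 95% interval 50.1 to 52.5), 2.19 times the 23.4% ± 0.506 (SD) of random placements on the same arms (one-sided permutation p = 0.001, the smallest the placements can give). Of 4 equal groups by score, the share was 65.0% in the strongest and 42.9% in the weakest. Coding exons held 0.879% of summits against 16.7% at random, and 3' UTRs held 1.42% against 4.97%. The 5' UTRs held 6.10% against 3.39%, introns 50.1% against 42.8%, and intergenic sequence 39.1% against 30.5%. Each of these departures had a two-sided permutation p of 0.002, the smallest possible here. Of the 2607 summits within 500 bp of a coding TSS, 83.9% lay upstream of it, at a median position of -118 bp.

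**Figure D2:**
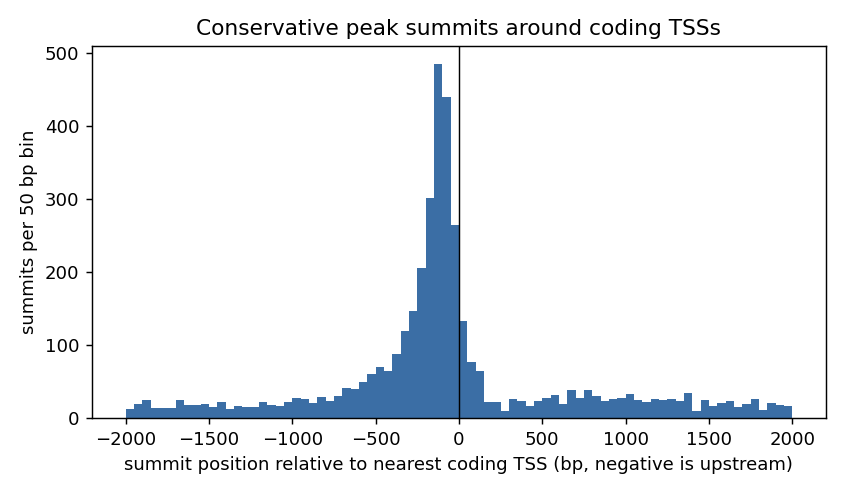
Number of conservative peak summits per 50 bp bin (y axis) by position relative to the nearest coding TSS in bp (x axis, negative values upstream). Within 500 bp the median position was -118 bp.

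Chromosome X carried more bound sites than its length gives, and chromosomes 4 and Y carried few. The X arm had 1418 summits, or 60.4 per Mb, 1.21 times its expected share (exact binomial test, exact adjusted p = 1.44e-14 over 7 arms). Chromosome 4 had 3 summits (ratio 0.0453, exact adjusted p = 5.04e-24) and Y had 1 (ratio 0.00589, exact adjusted p = 4.98e-72). Arm 2R was slightly below expectation (ratio 0.930, exact adjusted p = 0.00957). Arms 2L, 3L and 3R had ratios of 1.04, 1.03 and 0.986, with exact adjusted p of 0.152, 0.229 and 0.539. These tests count summits as independent units, but conservative peaks lay in runs. Chained within 10000 bp they formed 2826 clusters, so the arm p-values overstate the evidence. Expected shares came from sequence length alone. The copy number of X and Y, and how much of each arm reads can be placed on, were not taken into account. The few summits on 4 and Y may therefore not reflect binding.

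Core promoter elements were more frequent at the summits than in either background, AT-rich motifs were so against the flanks alone, and the bicoid-type core TAATCC did not pass the test in the flank draw used. The DNA replication-related element TATCGATA was in 1.42% of windows reaching 50 bp either side of the summit, against 0.205% of equal windows 500 bp away (odds ratio of discordant windows 6.93, exact adjusted p = 5.34e-16, exact McNemar test over 17 motifs). Motif 1, GGTCACAC, was in 0.733% against 0.205% (odds ratio 3.77, exact adjusted p = 1.02e-05). Against dinucleotide-preserving shuffles of the summit windows their odds ratios were 7.46 (exact adjusted p = 7.99e-16) and 7 (exact adjusted p = 3.17e-08). The Mef2 motif YTAWWWWTAR reached 7.31% against 2.70% (odds ratio 2.82, exact adjusted p = 2.04e-34), and the Antp-type core TAATTA 10.7% against 5.48% (odds ratio 2.07, exact adjusted p = 1.10e-28). The caudal or Abd-B type core TTTATKR (odds ratio 1.76, exact adjusted p = 1.85e-31) and the GATA motif WGATAAR (odds ratio 1.501, exact adjusted p = 2.79e-10) were also more frequent at summits than in flanks. Against the shuffles Mef2 (odds ratio 1.04, exact adjusted p = 0.602) and GATA (0.925, exact adjusted p = 0.270) showed no difference, and TAATTA (0.817, exact adjusted p = 7.25e-04) and TTTATKR (0.894, exact adjusted p = 0.0172) were less frequent. GAGAG, the GAGA factor element, was less frequent than in flanks (8.76% against 13.5%, exact adjusted p = 9.97e-18), as was the simple repeat CACACACA (1.08% against 3.33%, exact adjusted p = 5.32e-19). Both turned direction against the shuffles, with odds ratios of 1.36 (exact adjusted p = 2.29e-05) and 5 (exact adjusted p = 2.31e-09).

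TAATCC, the core bound by homeodomains of the Ptx1 class, was in 3.81% of summit windows and 3.34% of flank windows (odds ratio 1.15, exact adjusted p = 0.174). TAAGCC, a weaker bicoid-type core, was in 4.37% against 3.41% (odds ratio 1.29, exact adjusted p = 0.00628), with 1.42 against the shuffles (exact adjusted p = 3.98e-04) and a median of 1.24 over 1000 other flank draws, of which 808 gave an unadjusted p below 0.05. The letters of TAATCC written backwards, CCTAAT, gave 4.04% against 2.92% (odds ratio 1.40, exact adjusted p = 6.62e-04). The calls for TAATCC and TAAGCC depended on which side each flank was drawn from. Over the same 1000 draws, chosen after seeing the data, the TAATCC odds ratio ranged from 1.04 to 1.46 with a median of 1.25, and 784 draws gave an unadjusted p below 0.05. For CCTAAT the median was 1.35. Among the 90 distinct orderings of the 6 letters, TAATCC ranked 61 in the fixed draw, with a median rank of 49 over 200 other draws. Against the shuffles TAATCC was less frequent (odds ratio 0.796, exact adjusted p = 0.0153), and so was the control CCTAAT (0.782, exact adjusted p = 0.00678). The strongest of the 4 score groups had TAATCC in 4.57% of windows and the weakest in 3.52% (odds ratio 1.31, Fisher's exact test, p = 0.139). Within strata of GC content, chosen after seeing the data, the odds ratio was 1.24 (permutation p = 0.265).

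**Figure D3:**
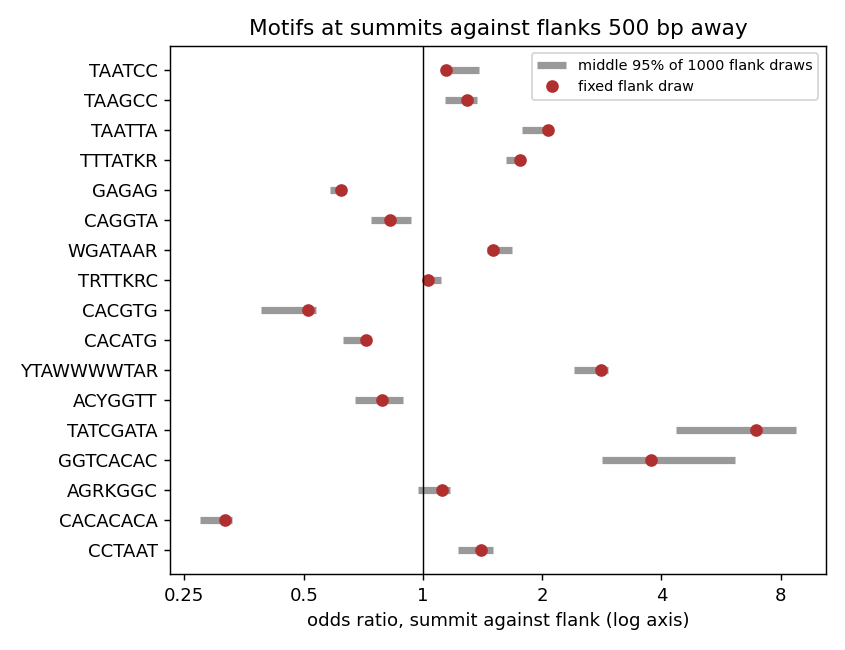
Odds ratio of discordant windows, summit against flank (x axis, log scale), for 17 motifs (y axis), with red points for the flank draw used in the text and grey bars for the middle 95% of 1000 other draws. TATCGATA lay at 6.93 and TAATCC at 1.15.

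Ribosomal protein genes were bound more often than other coding genes. Of 93 ribosomal protein genes, 61 had a summit within 1000 bp of a TSS (65.6%, exact 95% interval 55.0 to 75.1), against 26.4% of other coding genes (Fisher's exact test, odds ratio 5.30, exact adjusted p = 2.79e-14 over the lists). RpL34b (score 804), RpS27 (673), RpL32 (598) and RpL23A (569) had the strongest peaks. Of 19 germline and early maternal genes, 11 were bound (57.9%, interval 33.5 to 79.7, exact adjusted p = 0.0224), among them piwi (437), swa (410), bcd (330) and bgcn (318). Against gene sets matched on the number of TSSs and gene length the germline list had a permutation adjusted p of 0.0847.

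Genes for chemoreceptors, digestive proteases and glycosidases, and chorion and male reproductive proteins were rarely bound. Of 179 chemoreceptor genes, 5 were bound (2.79%, exact adjusted p = 1.47e-16), including Or88a, Gr32a, Ir94c and Ir60e. Without replicate 1 and without replicate 2 the share was 1.12% (exact adjusted p = 2.08e-15 and 7.32e-17). With a 500 bp window none was bound, and with a 2000 bp window 7.26% were (exact adjusted p = 1.72e-19 and 1.34e-15). Mal-A5 was the only bound member of 45 digestive protease and glycosidase genes (2.22%, exact adjusted p = 1.00e-04). Cp190 was the only bound member of 54 genes of the chorion and male reproductive list (1.85%, exact adjusted p = 7.52e-06). Cp190 encodes a chromatin insulator protein and entered that list through its symbol alone, as did Cp110, Acp1, Acph-1 and Acp65Aa. With these 5 dropped, a choice made after seeing the data, none of the list was bound (exact adjusted p = 1.62e-06). None of the 111 replication-dependent histone genes was bound (upper exact 95% bound 3.27%, exact adjusted p = 1.78e-14), but these genes form a multicopy array in which peaks are uncertain. All list tests count genes as independent units, which the copies of an array are not. The bound and the p-values for histone genes, with matched sets too, therefore overstate the evidence. In matched gene sets the expected shares were 23.2% for chemoreceptors, 18.6% for digestive, 17.5% for chorion and male reproductive and 11.4% for histone genes. Their permutation adjusted p were 0.00133, 0.0104, 0.003 and 0.00133, in the same order.

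None of the lists that follow passed the test of a difference from other coding genes within 1000 bp of a TSS. The head and paired-class homeobox list had 6 of 28 genes bound (21.4%, or 14.3% without replicate 1, exact adjusted p = 0.767 and 0.578), among them Poxm (score 515), PHDP (356), bcd (330) and Ptx1 (123). Of 8 Hox cluster genes only Dfd was bound (score 161, exact adjusted p = 0.767), and without replicate 1 none was. Of 20 gap and pair-rule genes cnc and cad were bound (10%, exact adjusted p = 0.282), and 5% were bound in the list of either replicate and in the other series list. Segment polarity and signalling genes had 11 of 26 bound (42.3%, exact adjusted p = 0.219), with spi (659), nkd (425), aos (401) and brk (346) strongest. This list passed with a 2000 bp window (57.7%, exact adjusted p = 0.0321) and when any summit in the gene body or 1000 bp upstream was counted (80.8%, exact adjusted p = 9.47e-07). For the 42.3% within 1000 bp, matched gene sets gave an expected 37.6% and a permutation adjusted p of 0.875. The 2 wider definitions were not tested against matched sets. Endoderm and gut genes had 6 of 20 bound, led by bowl (869), Myo61F (247), lin (202) and pnr (92.3), with exact adjusted p = 0.843. Without replicate 2 the share was 15%, and without replicate 1 it was 40%. Among Malpighian tubule genes Dh31-R (454) and Irk1 (434) were bound (2 of 17, exact adjusted p = 0.540).

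In the mesoderm and muscle list 8 of 26 genes were bound (exact adjusted p = 0.767), including tin (761), sls (474), mbc (427) and rols (264). The neural list had 6 of 28 bound (21.4%, exact adjusted p = 0.767), but 10.7% in the list of either replicate and in the other series list, with elav (999) and brat (764) far above scrt (107) and Ddc (84.7). Only amn and sNPF were bound among 22 neuropeptide genes (exact adjusted p = 0.219), and trh, grh and rib among 18 genes of trachea and epidermis (exact adjusted p = 0.720). Of 26 heat shock genes 9 were bound (exact adjusted p = 0.685), with Hsp27 (1377), Hsc70-5 (412), Hsp26 (342) and Hsc70-4 (288) strongest. V-ATPase genes had 9 of 33 bound (exact adjusted p = 1), led by Vha100-2 (740), Vha14-1 (440), Vha16-5 (398) and Vha68-1 (301). Proteasome genes had 11 of 48 bound (exact adjusted p = 0.767), led by Rpn3, Prosbeta2, Rpn6 and Rpn5. Oxidative phosphorylation genes had 22 of 92 bound (exact adjusted p = 0.767), led by Cyt-c-d (950), Cyt-c-p (766), ND-MWFE (585) and ND-ASHI (538).

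**Figure D4:**
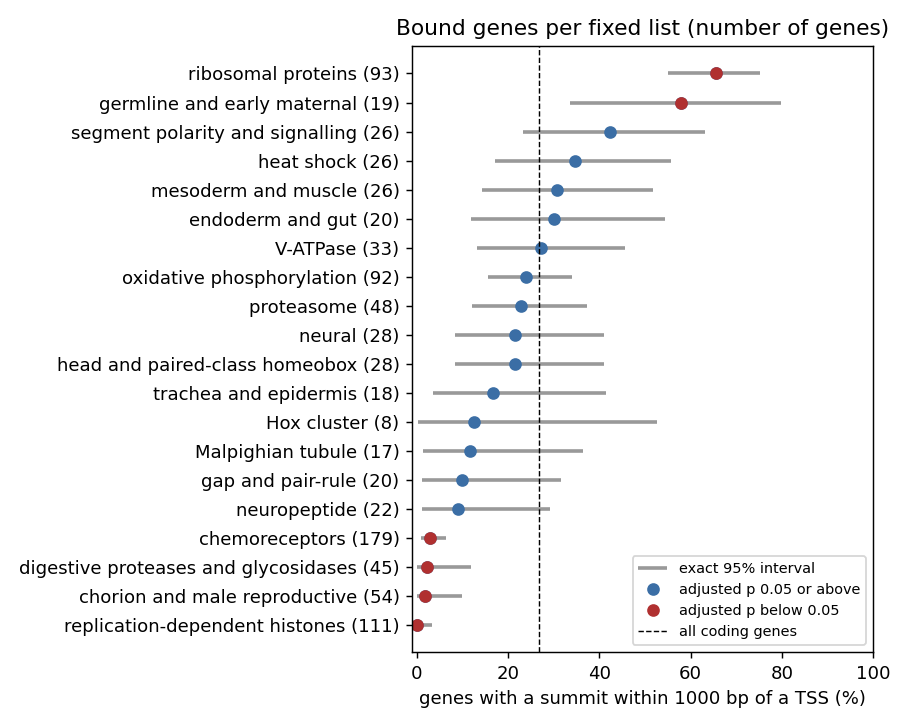
Percent of genes with a conservative summit within 1000 bp of a TSS (x axis) for each of 20 lists (y axis, number of genes in brackets), with exact 95% intervals as grey lines, lists with adjusted p below 0.05 in red and all coding genes as a dashed line at 26.7%. Ribosomal protein genes lay at 65.6%.

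Annotated starts of tRNA, snoRNA and microRNA genes had a summit nearby less often than those of coding genes. Within 500 bp of the start, 6.55% of 290 tRNA genes (exact adjusted p = 3.14e-13), 3.35% of 269 snoRNA genes (exact adjusted p = 3.12e-18) and 3.46% of 260 microRNA genes (exact adjusted p = 8.14e-18) had a summit, against 22.8% of coding genes by Fisher's exact test. Of 32 snRNA genes, 8 had one (25%, odds ratio 1.13, exact adjusted p = 0.833). Coding genes were not matched to these classes on the number of TSSs or gene length, so the gaps can include those differences. Some neighbouring tRNA genes shared the same peak, so genes are not independent units. Some peaks near snoRNA, snRNA or tRNA genes were also counted for a coding gene. Whether the annotated start of an RNA gene marks its promoter was not assessed, so the shares do not measure avoidance of RNA gene promoters.

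Peaks that passed the threshold lay at promoters more often than those that failed it. Of 6824 passing peaks 51.3% had a summit within 1000 bp of a TSS, against 25.9% of 83473 failing peaks (odds ratio 3.01, 95% interval 2.87 to 3.17). TAATCC was in 3.81% of passing and 3.08% of failing windows (odds ratio 1.25, Fisher's exact test, p = 0.00129). With failing peaks matched on GC content the TAATCC odds ratio was 1.13 (Fisher's exact test, p = 0.167). Matching left 7791 failing peaks, so this test also had fewer peaks. Mean GC content was 33.3% ± 9.85 (SD over peaks) in passing summit windows and 47.1% ± 9.75 in failing ones.

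**Figure D5:**
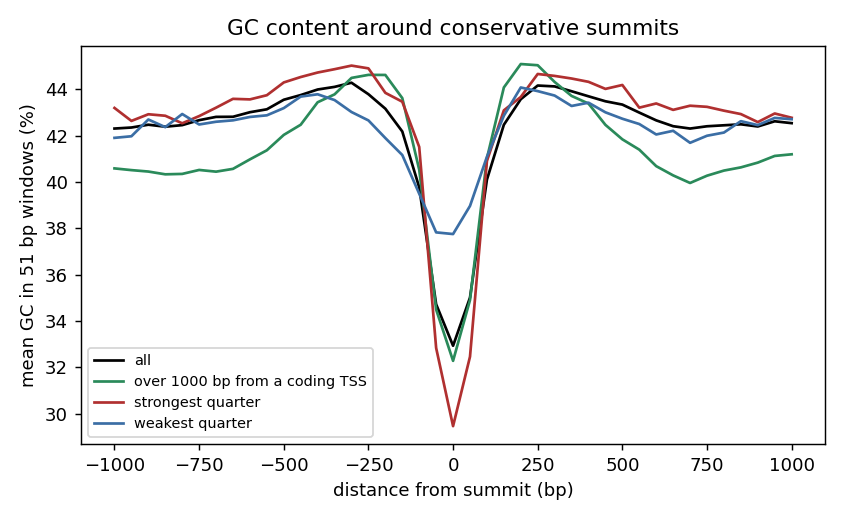
Mean GC content in 51 bp windows (y axis, percent) by distance from the conservative summit in bp (x axis), for all peaks, those over 1000 bp from a coding TSS, and the strongest and weakest of 4 groups by score. At the summit GC was 29.5% in the strongest group and 37.8% in the weakest.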

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

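The tests of repeat sequence and of removal by position were chosen before their results were seen, and the 3R comparison after. On the named chromosomes 123 peaks scored at or above the IDR minimum and were absent from the conservative list, a signal outside the main comparisons. They included the third-ranked peak of the replicate pair (2L, 480882 to 481272, score 3263, in an intron of ush and 1403 bp from the start of cbt) and peaks in introns of Lk6 (score 2077), larp (1361), tara (1247) and trx (1195). Arm 3R held 84 of the 123 (68.3%), against 23.1% of conservative peaks. The absent peaks lay in runs, so they are not independent: chained within 10000 bp they formed 58 clusters, 28 with several peaks and the largest with 10, and 1 conservative peak lay inside them. Of these clusters 42 were on 3R (72.4%), against 24.8% of 2826 clusters of conservative peaks (Fisher's exact test, odds ratio 7.94, p = 7.69e-14).

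Repeat sequence does not account for them as a set: 13.8% (17 of 123, exact 95% interval 8.26 to 21.2) had a mostly soft-masked summit window, against 12.4% of conservative peaks. Removal by position in every list remains a candidate explanation, since 1.63% (2 of 123) overlapped a peak kept in another thresholded list. Of the 123, 116 overlapped a high-scoring peak absent from the other series list, 95 one absent from the replicate 1 list and 90 one absent from the replicate 2 list. What defined the positions stays open, and no biological explanation was tested.

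The conservative list also held 16 peaks on scaffolds outside the named chromosomes, with scores from 56.2 to 149. They were left out of the comparisons by position, sequence and gene. Of 47 scaffold peaks of the replicate pair at or above the IDR minimum, 31 were absent from the conservative list.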

How the results depend on the processing

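Of 58 alternatives to the main results, 51 were counted as unchanged. For single tests that meant the same direction and side of the threshold. For numbers of lists or RNA classes it meant a similar number called, and for list sizes a ratio within the interval. Replicate overlap, promoter share, X excess, the same 3 RNA classes and the list sizes were unchanged under all that were run. The number of gene lists called stayed between 5 and 7 (6 in the report). The germline list lost its call with matched sets, and segment polarity and signalling gained one with a 2000 bp window and with gene bodies. The TAATCC odds ratio passed the threshold with overlapping peaks merged (1.30), with a 51 bp window (1.32) and with the flank on the opposite side (1.39, chosen after seeing the data), and turned to 0.796 against dinucleotide shuffles. The opposite-side alternative differed from the main test in the side of each flank alone, so that side accounts for its change. A redrawn flank side also enters the alternative with merged peaks, and the other causes were not tested. The TAATCC odds ratio of passing against failing peaks lost its call with GC matching (1.13), which also cut the failing peaks to 7791. The replicate score correlation moved to 0.92 in passing peaks and to 0.36 on ranks. Of 200 alternatives for single lists 15 changed direction or call. Lists that never passed turned direction: with the strongest peaks alone, endoderm and gut (15%) and oxidative phosphorylation (20.7%); with matched sets, endoderm and gut (30%), mesoderm and muscle (30.8%) and proteasome (22.9%); with a 500 bp window, proteasome (22.9%); with gene bodies, Hox (50%), neural (32.1%), trachea and epidermis (38.9%) and V-ATPase (27.3%). With 1 replicate left out in turn, endoderm and gut ranged from 15% to 40% and oxidative phosphorylation from 21.7% to 22.8%. The cause was not tested. Read depth is unknown, so what it limits was not assessed.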

Other observations

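The tests of the promoter, the TAATCC core and the pair of unmasked windows were chosen after the results were seen. So were the comparisons of motifs by score other than TAATCC. The X ratio without chromosomes 4 and Y was not set beforehand. The other tests of the GC fall and the X excess were chosen before their own results were seen, but after those patterns were. The motif content of strong and weak sites differed, and so did their GC content. TAATTA was in 12.4% of windows in the strongest of 4 equal groups by score and 7.21% in the weakest (Fisher's exact test, adjusted p = 2.01e-06 over 17 motifs), and the Mef2 motif in 9.79% and 4.51% (exact adjusted p = 3.20e-08). By the same exact test TATCGATA went the other way, with 0.586% and 1.88% (adjusted p = 0.00248), as did motif 1, GGTCACAC, with 0.293% and 1.23% (adjusted p = 0.00584), and GAGAG, with 6.21% and 11.96% (adjusted p = 3.31e-08). GC content was 30.02% in the strongest group and 37.8% in the weakest. Compared within 10 strata of GC content, TAATTA had an odds ratio of 1.08, Mef2 1.39, TATCGATA 0.517, GGTCACAC 0.664 and GAGAG 0.708, with permutation adjusted p of 0.796, 0.112, 0.127, 0.796 and 0.0792. Before adjustment Mef2 (permutation p = 0.0263), TATCGATA (0.0374) and GAGAG (0.014) stayed below 0.05, so GC content is not shown to account for these. CACACACA (0.241, permutation adjusted p = 0.0484) and the CTCF core AGRKGGC (2.08, permutation adjusted p = 0.00357) passed, the latter without a difference before stratification (0.794, exact p = 0.259). In simulated peaks this test found CAGGTA planted in the strongest 75 of 6000 in all 10 draws, and in the strongest 30 in 30% of them. Small differences can therefore be missed. Where the simulated score separated peaks by GC content, CAGGTA planted in the strongest 300 was missed. The lowest GC stratum held 276 of the strongest and 102 of the weakest windows, and the highest 51 and 260. No AT-rich motif was planted, so the power for TAATTA and Mef2 is not known.

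GC content fell by 10.1 percentage points from 500 bp away to the summit (95% interval 9.79 to 10.4 over 6824 peaks). Promoter sequence does not account for it, since the fall was 9.18 points at the 3579 summits over 1000 bp from a coding TSS. Dropping summit windows with any soft-masked base left 2.88 points, below the 5 points set beforehand, but masking follows GC content and the flanks were not treated alike. Where neither window was masked the fall was 6.81 points (1797 pairs), which argues against masked sequence as the whole cause. TAATCC ranked 61 of 90 orderings of its letters, and between 28 and 67 over 200 other flank draws, which argues against that core as the mark of these summits, and open chromatin or fragment bias stays open without a control.

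The X excess was weighed against 3 technical explanations. With expectation from the number of coding TSSs the X ratio was 1.23 (95% interval 1.18 to 1.29), and from unmasked length 1.22 (1.16 to 1.27), so neither accounts for it. Failing peaks had a ratio of 1.01 (0.998 to 1.03), below the passing interval of 1.16 to 1.27, which argues against an excess of all reported positions. Without chromosomes 4 and Y in the expectation the ratio was 1.17 (1.12 to 1.23). All these intervals treat summits as independent, although neighbouring peaks lay in runs, so they are likely too narrow. A binding preference for X may be stated only as a hypothesis, and the sex of the embryos and the control were not analysed here.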
